A study of Rattus norvegicus with 12 samples.

How the data were processed

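RNA of the cervical cord segments was measured in 12 hemicord samples of 6 rats, 3 rats 3 days and 3 rats 14 days after right brachial plexus root avulsion, on 1-colour Agilent arrays (Cy3) with probes for mRNAs and long non-coding transcripts. Per the labels' protocols, ribosomal RNA was removed and the RNA amplified with oligo(dT) and random primers, so transcripts without a poly(A) tail can be measured. Groups, rat numbers and days were taken from the sample labels. The rats are separate animals, and the ipsilateral and contralateral hemicords of a number come from the same rat.

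The scanner tables were made with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes. Per the file headers, their processed signal is a spot intensity on a linear scale, background-subtracted and spatially detrended within the array and not scaled between arrays, and the median signal and median local background are raw intensity values. The above-background, saturation and outlier marks of each spot are 0 or 1 calls made by the same program, per the file headers. The array design names genome build rn4 in the headers, and no coordinates were used. The authors also deposited a table of processed values for the same 12 arrays, on a log2 scale. Each of its columns correlated at 0.9944 to 0.9994 with the log2 signals of its own array and at no more than 0.9922 with any other, the values of a rank differed by at most 0.299 between columns, and the column medians were 7.593 to 7.598. It therefore holds log2 values that were quantile normalized over the arrays and not centred by gene, with higher meaning brighter. The program and background step behind it are not given in the sources used here. Of its 24529 rows, 24484 matched a probe, and it was used only as an alternative. All 12 of its columns were used.

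The main values were log2 of the processed signal minus the 75th percentile of that array, in R 4.3.3 with limma 3.58.1 and the package data.table (version 1.17.8). Control spots and spots marked as outliers (484 to 588 of 42136 per array) were left out, no spot was saturated, and spots of a probe were averaged. Of 24684 probes, 19707 were tested, those well above background on every array of at least 1 group. The 75th percentile of the signal was 2666 to 3800 on the day 3 arrays and 845.6 to 1159 on the day 14 arrays, and the median ratio of signal to local background was 8.2 to 13.2 and 4.66 to 7.32. The number of arrays limits the precision. Correlations between arrays were 0.9599 to 0.9944 within a group and 0.8984 to 0.9892 between groups, over probes, which are not independent replicates.

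Probes were named through a RefSeq table of the rat assembly GRCr8, used for names only, by accession without version: 14237 of 15286 mRNA accessions matched a symbol. The tested probes represent 11870 genes, 274 of them by more than 1 probe, and a gene was represented by its probe with the highest mean. The probes fall into classes by the kind of their name: 13088 tested RefSeq mRNA probes, 1346 RefSeq non-coding probes, 3115 with MR names, 424 uc. elements and 1734 with another accession. The latter 4 classes were left without gene symbols.

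All 12 arrays were fitted together with limma as 4 group means, which share 1 estimate of the spread with 8 residual degrees of freedom. Moderated 2-sided tests compared the sides within each day, the difference between the days of that change (interaction) and the days within each side, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Log2 changes are given as ipsilateral minus contralateral, or day 14 minus day 3, with their SE from this fit. Where all arrays of a group were not well above background for a probe, only a bound can be given: the mean of the brighter group against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal of any probe well above background, written as "at least N-fold".

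The 28 gene lists were fixed before the data were examined: axotomy response, motoneuron, pan-neuronal, interneuron, synapse, microglia, phagocyte activation, blood leukocyte, astrocyte identity, reactive astrocyte, oligodendrocyte and myelin, oligodendrocyte progenitor, vascular, meningeal and fibroblast, Schwann cell, sensory ganglion, erythrocyte, complement, cytokine and chemokine, interferon response, MHC class II, cell cycle, cholesterol synthesis, ER stress, p53 and apoptosis, scar matrix, immediate early and Hox genes. Each was tested against all other genes with camera of limma at a preset correlation of 0.01, adjusted over the 28 lists, and again with the correlation estimated from the residuals. A list is said to move where camera passed. Some genes are in more than 1 list. The program fry was run too. Its p tests whether the genes of a set move on balance in 1 direction, its mixed p whether they change in either direction, and neither compares the set with other genes.

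The rule for named genes was also set before the data were examined. For each comparison of the sides it takes the 10 largest increases and 10 largest decreases among probes with 1 symbol that passed and had the same direction in all 3 rats, leaving out symbols that are only a predicted locus. For the other comparisons it takes 5 and 5, without the condition on rats for the comparisons of days. In each list it takes up to 4 members with the smallest p, and among non-coding probes the 3 largest increases and 3 largest decreases. Values of such genes at the other day, and features named only because a count is 5 or lower, were chosen after the values were seen. Some results that the rule names are not reported here.

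Same-numbered hemicords deviated together from their group means, with correlations over probes of 0.488, 0.639 and 0.842 for rats 1, 2 and 3 and 0.256, 0.452 and 0.426 for rats 4, 5 and 6. Hemicords of rats 1 and 2, which share a slide, did so across the rats as well (0.532 and 0.47). At day 3 these correlations thus do not tell the rat from the slide. Across rats 4 and 5, which also share a slide, they were 0.136 and -0.093. The pairing itself comes from the labels, and the rat was fitted as a block as an alternative. Slide 1 held rats 1 and 2, slide 2 rat 3, slide 3 rats 4 and 5 and slide 4 rat 6, so the slide was fitted as a block for the comparisons of sides and as a random block (consensus correlation 0.617, and 0.577 for the rat) where each slide holds 1 day.

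Alternative settings chosen before the data were examined were quantile normalization, normexp background correction (offset 50) with quantile normalization, the authors' deposited log2 values, no filter on dim probes, only probes above background on all arrays, slide as a block, a variance trend, thresholds with a 2-fold change, each array left out, the rat as a fixed or random block, only the groups compared and, for lists, an estimated correlation, fry and the mean over all probes of a gene. Normexp was run on the median signal and the median background because the scanner tables used here have no mean signal column. Chosen after seeing the data were the slide as a random block, rat 3 or rat 6 left out, only the slide with 2 rats, the mean of the Schwann cell markers as a covariate and the list tests of the interaction.

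The tests were checked on simulated data of 19656 probes with 200 of them changed by log2 sizes of 0.5, 1, 2 and 4. For the day 3 comparison of sides 6%, 32%, 84% and 90% of these were recovered, for day 14 8%, 48%, 72% and 88%, and for the interaction 0%, 12%, 60% and 78%, with no wrong sign. Of the unchanged probes 0, 2 and 0 were called. With the rat as a block 8%, 52%, 92% and 98% were recovered at day 3 and 6 unchanged probes were called. For the comparisons of days 16%, 36%, 74% and 96% were recovered ipsilaterally and 8%, 38%, 70% and 90% contralaterally, with 18 and 10 unchanged probes called. A list shifted by design was found in every comparison, and in the interaction 1 list that was not shifted was called as well, without and with the rat as a block. The simulated probes were drawn independently of each other and without a slide effect. Genes of a list were thus uncorrelated there, while the correlation estimated in the real data reached 0.904 for the erythrocyte markers. False calls of lists with correlated genes at the preset correlation were therefore not checked.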

Results

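RNA was measured in the cervical spinal cord of 6 female Sprague-Dawley rats after the right brachial plexus roots, from the fifth cervical to the first thoracic level, had been torn out of the cord. In this injury the axons of motoneurons are severed at the cord surface, and the torn roots and their dorsal root ganglia were removed at the operation. The same segments were taken 3 days after avulsion from rats 1, 2 and 3 and 14 days after it from rats 4, 5 and 6. Each cord was divided along the midline into the hemicord of the avulsed side (ipsilateral) and that of the uninjured side (contralateral). This gave 12 samples, 3 rats in each of 4 groups, each on its own 1-colour array with probes for mRNAs and for long non-coding transcripts. Of the probes on an array, 71.8% to 75.1% were well above background at day 3 and 74.7% to 82.4% at day 14. The title of the series names the question: which mRNAs and long non-coding RNAs change with time after avulsion, before motoneurons are lost. The contralateral hemicords of the same rats served as the control. The SEs and p-values below come from group means that do not pair the hemicords of a rat, unless the rat as a block is named. No unoperated rats were analysed here, so a change common to both sides was not measured against an uninjured cord.

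At day 3 genes of injured neurons, dividing cells, microglia and inflammatory signalling were among those raised in the ipsilateral hemicord, but as lists none of these passed with an estimated correlation (adjusted p = 0.0658, 0.0658, 0.0818 and 0.25). Atf3, a transcription factor induced in neurons whose axons are cut, rose 16.6-fold (log2 change 4.06 ± 0.23, SE, n = 3 rats, adjusted p = 9.03e-05). Ankrd1, a nuclear cofactor best known from stretched muscle, rose 50.1-fold (5.65 ± 0.33, adjusted p = 9.03e-05). Hamp, which encodes the iron-regulating hormone hepcidin, rose 63.4-fold (5.99 ± 0.51, adjusted p = 0.000727). Serpinb2, an inhibitor of plasminogen activators, was not well above background in any contralateral sample and rose at least 78.4-fold (adjusted p = 0.000727). The largest falls were those of Slc36a2, an amino acid transporter (-5.49 ± 1.16, adjusted p = 0.0426), and Sfrp5, a secreted inhibitor of Wnt signalling (-5.33 ± 0.92, adjusted p = 0.0178).

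Further large increases at day 3 were those of Reg3b, a secreted lectin (5.98), Csrp3, a LIM protein of muscle that is also made in injured neurons (5.13), Lce1f, a gene of the skin's cornified envelope (4.19), the cytokine Il24 (3.98) and Hsd3b1, an enzyme of steroid hormone synthesis (3.92). Their adjusted p lay between 0.000115 and 0.033. Reg3g, a relative of Reg3b, was not well above background in the contralateral samples and rose at least 15.9-fold. After Slc36a2 and Sfrp5 the falls were those of Mrap, an accessory protein of the melanocortin receptor (-3.32, adjusted p = 0.0405), Rem2, a GTPase that restrains calcium channels (-2.14), and Rprm, a mediator of cell cycle arrest (-2.01). Smaller falls were those of Irag1, a substrate of cGMP-dependent kinase (-1.72), the monooxygenase Fmo2 (-1.60) and the focal adhesion protein Lims2 (-1.51). The ipsilateral samples were not well above background for Abca15, a lipid transporter, or Defa8, a defensin, which fell at least 5.73-fold and 2.18-fold (adjusted p = 0.0418 and 0.0408). Abca15 did not pass with the rat as a block (adjusted p = 0.0527). The Schwann cell markers, described with the other cell types, had lower list means on the ipsilateral side in all 3 rats, but their list did not pass with an estimated correlation (adjusted p = 0.25). Slc36a2, Sfrp5, Abca15 and Mrap fell in all 3 rats too. The rule for named genes requires this, so the match is no support for a link.

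**Figure D1:**
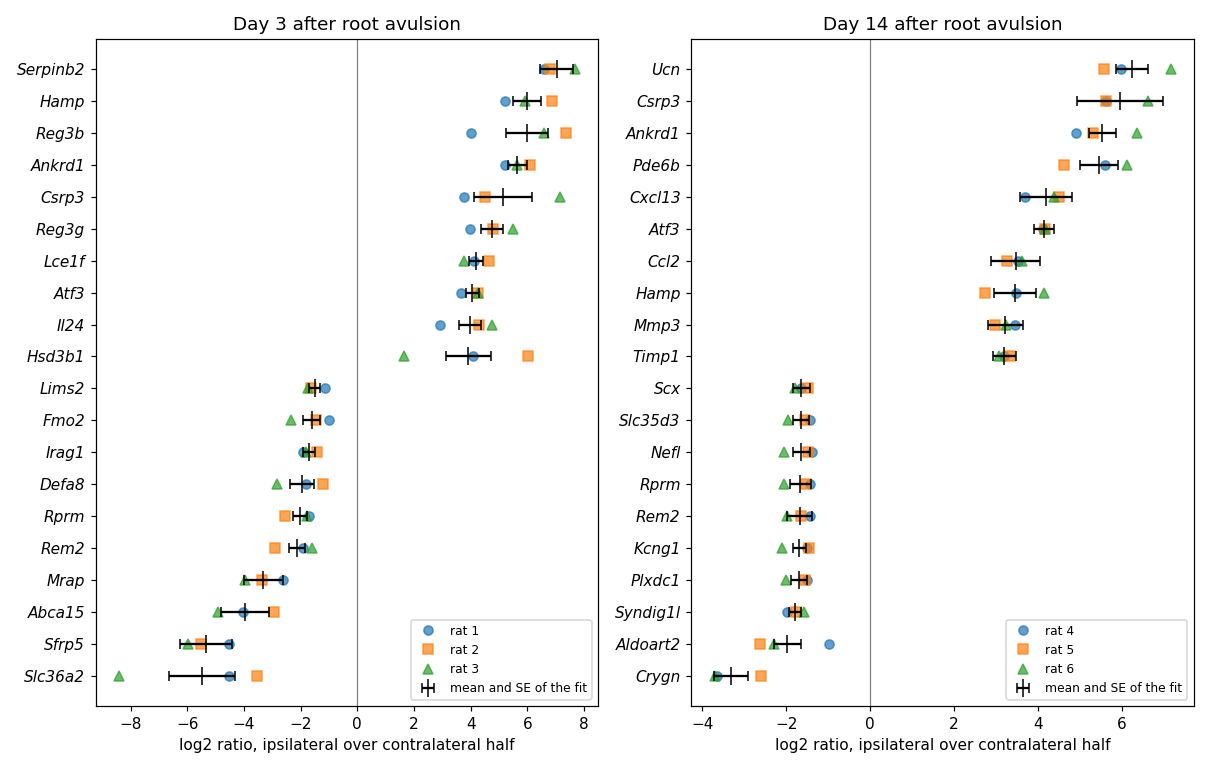
Log2 ratio of the ipsilateral over the contralateral hemicord for the 10 genes with the largest increase and the 10 with the largest decrease at day 3 (left) and day 14 (right), by rat (coloured symbols) and as the mean and SE of the fit (black). Atf3 and Ankrd1 are among the largest increases on both days, at 4.06 and 5.65 on day 3 and 4.15 and 5.53 on day 14.

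Among genes of the axotomy response, those induced in neurons by cutting their axons, 7 of 21 measured members rose at day 3, none fell and 14 did not pass. Adjusted over the list alone, 14 rose. Besides Atf3 these were led by Ecel1, a neuronal peptidase (2.64 ± 0.22), Sox11, a transcription factor of growing neurons (2.09 ± 0.25), and Gadd45a, a stress-response gene (1.11 ± 0.13). The list moved up against all other genes (median 0.67, adjusted p = 3.36e-15, adjusted p = 0.0658 with an estimated correlation). Of the 10 motoneuron markers none passed at day 3, and 1 fell when adjusted over the list alone. Slc5a7, the choline transporter of cholinergic neurons, was at -0.69 ± 0.16 (adjusted p = 0.0572, and 0.0232 with the rat as a block) and Slc18a3, the vesicular acetylcholine transporter, at -0.58 ± 0.23 (adjusted p = 0.381). Their list did not pass (median -0.36, adjusted p = 0.0761). It passed with quantile scaling (adjusted p = 0.0412), without the contralateral sample of rat 1 (adjusted p = 0.0499) and without that of rat 3 (adjusted p = 0.0337). None of the 13 pan-neuronal markers passed. They had a median of -0.23 (adjusted p = 0.0839, but 0.0195 with quantile scaling, 0.0194 with normexp and 0.0401 without the contralateral sample of rat 1). The 20 synapse genes moved down together (median -0.18, adjusted p = 0.00427, adjusted p = 0.291 with an estimated correlation) with no member past the threshold. Gria3, a glutamate receptor subunit, was at -0.51 ± 0.13 (adjusted p = 0.0854). Of the 13 interneuron markers, Pdyn, the precursor of dynorphin, rose (1.50 ± 0.32, adjusted p = 0.0444) and the others did not pass. The list did not move (adjusted p = 0.684), with a median of -0.16 and a mean of 0.06.

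Microglia markers rose at day 3 in 7 of 20 members and in 16 when adjusted over the list alone (median 1.13, adjusted p = 1.65e-15, adjusted p = 0.0818 with an estimated correlation). C1qc, a chain of complement C1q, rose 4.77-fold (2.25 ± 0.30). Fcer1g, an adaptor of Fc receptors (1.47), the leukocyte tetraspanin Cd53 (1.46) and Cx3cr1, the fractalkine receptor (1.31), rose less. Of 18 complement genes 5 rose, 8 when adjusted over the list alone (median 0.75, adjusted p = 1.53e-08, adjusted p = 0.105 with an estimated correlation). Cfp, or properdin (1.37), and C1qb (1.60) were among them. The cytokine and chemokine list had 4 of 25 members higher, 6 over the list alone (median 0.80, adjusted p = 5.98e-07, adjusted p = 0.25 with an estimated correlation). These were Il6 (3.91 ± 0.58), the monocyte chemoattractants Ccl2 (3.44 ± 0.58) and Ccl7 (2.64 ± 0.41), and Il1rn, an antagonist of interleukin 1 (1.34 ± 0.27). Cell cycle genes rose in 8 of 17 members, 14 over the list alone (median 1.22, adjusted p = 3.36e-15, adjusted p = 0.0658 with an estimated correlation). Examples are the mitotic cyclins Ccnb1 (1.93 ± 0.31) and Ccnb2 (1.74 ± 0.31) and the mitotic kinesin Kif20a (2.07 ± 0.39).

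At day 3, of 10 genes of the MHC class II pathway, which presents antigen to T cells, RT1-DMb (1.67), Cd86 (1.43) and RT1-DMa (1.36) rose. The same number rose over the list alone, 3 (median 0.43, adjusted p = 0.00024, adjusted p = 0.216 with an estimated correlation). Of 15 blood leukocyte markers Arg1, or arginase (1.95 ± 0.17, adjusted p = 0.000862), and Lcp2, a T cell adaptor (1.28), rose. Adjusted over the list alone 3 did (median 0.65, adjusted p = 0.0024, adjusted p = 0.13 with an estimated correlation, adjusted p = 0.062 without the ipsilateral sample of rat 1). Of 15 phagocyte activation genes only Cd68, a lysosomal protein of macrophages, rose (1.75 ± 0.32), 1 over the list alone (median 0.24, adjusted p = 0.00427, adjusted p = 0.242 with an estimated correlation). Of 22 reactive astrocyte genes Cd14, a receptor for bacterial lipopolysaccharide that myeloid cells also make, rose (2.20 ± 0.28), 3 over the list alone (median 0.57, adjusted p = 1.41e-05, adjusted p = 0.216 with an estimated correlation). Timp1, a metalloproteinase inhibitor, was at 1.11 ± 0.28 (adjusted p = 0.088, and 0.016 with the rat as a block). The 13 genes of p53 and apoptosis moved up together (median 0.52, adjusted p = 8.61e-06, adjusted p = 0.051 with an estimated correlation) with none past the threshold and 5 over the list alone. The 24 interferon response genes had no member past the threshold and a median of 0.12 (adjusted p = 0.0484, adjusted p = 0.729 with an estimated correlation). This list passed only narrowly. Its adjusted p was 0.0656 with quantile scaling, 0.404 without the ipsilateral sample of rat 1, 0.11 without that of rat 2, 0.0933 without the contralateral sample of rat 1 and 0.332 without that of rat 3. The 18 genes of cholesterol synthesis moved down (median -0.24, adjusted p = 0.0119, adjusted p = 0.508 with an estimated correlation) with none past the threshold. Among 9 immediate early genes Nr4a1, an activity-induced nuclear receptor, fell (-0.88 ± 0.16, adjusted p = 0.0198) and the list did not move (adjusted p = 0.247). The lists of astrocyte identity (adjusted p = 0.948), oligodendrocyte progenitors (adjusted p = 1, mean -0.05 although the test pointed up), ER stress (adjusted p = 0.305), scar matrix (adjusted p = 0.684) and Hox genes (adjusted p = 0.397) did not move. In the scar matrix list Ncan, or neurocan, was at 0.95 ± 0.23 (adjusted p = 0.0707, and 0.0309 with the rat as a block). None of their members passed, nor did any of the 14 oligodendrocyte and myelin genes (median -0.16, adjusted p = 0.0872, but 0.0126 with quantile scaling, 0.0107 with normexp and 0.00287 without the contralateral sample of rat 3).

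Of the 5 lists of vessels, blood and tissue around the cord 3 moved at day 3, all down. The 10 Schwann cell markers were lower on the ipsilateral side (median -1.24, mean -1.63, adjusted p = 0.000609, adjusted p = 0.25 with an estimated correlation). Their list means were -0.72, -1.32 and -2.86 in rats 1, 2 and 3. None passed over all probes and 7 fell when adjusted over the list alone. The peripheral myelin genes Prx and Pmp22 were at -3.94 (adjusted p = 0.13) and -1.04 ± 0.28 (adjusted p = 0.119). The list did not pass without the ipsilateral sample of rat 3 (adjusted p = 0.0755). The 5 sensory ganglion markers had list means of -0.40, -4.38 and 0.11 in the 3 rats (median -1.58, adjusted p = 0.0234, adjusted p = 0.489 with an estimated correlation and 0.0628 with the rat as a block). Without the contralateral sample of rat 2 their adjusted p was 0.478. The 10 meningeal and fibroblast markers had list means of 0.93, -0.14 and -2.37 and did not pass (adjusted p = 0.187). They did pass without the ipsilateral sample of rat 1 (adjusted p = 0.000602) or of rat 2 (adjusted p = 0.0333), and were called up with the Schwann cell marker covariate (adjusted p = 8.56e-06). The 13 vascular markers were lower (median -0.40, adjusted p = 0.0234, adjusted p = 0.216 with an estimated correlation), 2 over the list alone. They did not pass without the contralateral sample of rat 1 (adjusted p = 0.111), the ipsilateral sample of rat 3 (adjusted p = 0.305) or the contralateral sample of rat 3 (adjusted p = 0.0524). The 6 erythrocyte markers did not pass (median -0.82, adjusted p = 0.505) except with the rat as a block (adjusted p = 0.0349, and 0.281 with an estimated correlation as well). Without the ipsilateral sample of rat 3 the sensory ganglion markers did not pass either (adjusted p = 0.0533).

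Among long non-coding transcripts at day 3, 24 of the 3115 tested probes that carry a mouse- or rat-derived MR name changed, 18 higher and 6 lower (43 with the rat as a block, 25 higher and 18 lower). MRAK012306 rose 4.12-fold (2.04 ± 0.16, adjusted p = 0.000727). The transcripts MRuc008qeu and MRBC048721, not well above background in the contralateral samples, rose at least 6.68-fold and 2.21-fold (adjusted p = 0.00201 and 0.0497). MRAK142743 (-2.61 ± 0.49, adjusted p = 0.0252) and MRuc008lgr (-1.14 ± 0.17, adjusted p = 0.0101) fell, and MRuc009umr fell at least 2.5-fold (adjusted p = 0.0438). Of 1346 RefSeq non-coding probes 5 rose and none fell (20 and 4 with the rat as a block). These 5, named because they are few and not by the rule for named genes, were XR_008800 (1.56), XR_009380 (1.35), XR_006073 (0.95), XR_005904 (0.88) and NR_027983 (0.65). None of the 424 uc. elements, named for ultraconserved sequences, passed in the limma fit without a block, where 18 had an unadjusted p under the threshold, and with the rat as a block 6 did, all lower.

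In all, 425 of 19707 probes differed between the sides at day 3, 355 higher and 70 lower, of which 318 changed at least 2-fold. With the rat as a block 829 passed, 631 higher and 198 lower, 406 of them among the 425. The count rested on single samples: it was 120 without the ipsilateral sample of rat 1, 145 without that of rat 2 and 159 without the contralateral sample of rat 2. It was 261 with quantile scaling and 16, all higher, with only the 6 samples of day 3 fitted. With the mean of the Schwann cell markers as a covariate, chosen after seeing the data, it was 16 as well. With the slide as a block 1093 probes passed, all 425 included. The 355 higher and 70 lower probes kept their direction on both slides, with medians of 1.44 and -1.01 on that of rats 1 and 2 and 1.35 and -0.97 on that of rat 3. These probes were called on the same samples, which nearly fixes their direction, so this is no separate support. Of the 28 gene lists 16 moved, 11 up and 5 down, 15 of them with the slide as a block and 0 with an estimated correlation. Of these 16, all kept the sign of their mean on the slide of rats 1 and 2, and on that of rat 3 all but the interferon response (-0.09) and the sensory ganglion markers (0.11) did. The lists too were called on these samples. The calls of Serpinb2, Hamp, Reg3b, Ankrd1, Reg3g, Lce1f, Atf3, Il24, Rem2, Rprm, Irag1, Lims2, MRuc008qeu, MRAK012306, Ecel1, Gadd45a, Sox11, C1qc, Arg1, Cd14, Cfp and RT1-DMb held with any 1 of the 6 samples left out. The other genes and probes given above as past the threshold at day 3 kept their sign and lost the call without at least 1 sample, at adjusted p up to 0.189. With quantile scaling the calls of Slc36a2, Sfrp5, Mrap, Defa8, Fmo2, Csrp3, Lcp2, Il1rn, Cd86, Ccnb1, Ccnb2, Kif20a, MRAK142743, MRuc008lgr, XR_009380, XR_005904 and NR_027983 were lost too, with the sign kept and adjusted p from 0.0517 (Ccnb2) to 0.251 (Defa8).

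At day 14 genes of injured neurons, antigen presentation and complement were among those raised in the ipsilateral hemicord, and some motoneuron and neurofilament genes among those lowered. The motoneuron list, with 3 of 10 members past the threshold, did not pass with an estimated correlation (adjusted p = 0.0525). Ucn, the stress peptide urocortin, rose 75.4-fold (6.24 ± 0.37; n = 3 rats, adjusted p = 6.34e-05), and Ankrd1 and Atf3 rose 46.2-fold and 17.7-fold (5.53 ± 0.33 and 4.15 ± 0.23, adjusted p = 6.34e-05 for both). Cxcl13, which attracts B cells, rose 18.3-fold (4.19 ± 0.62, adjusted p = 0.0167), and Timp1 rose 9.16-fold (3.20 ± 0.28, adjusted p = 0.000669). Nefl, the neurofilament light chain, fell (-1.64 ± 0.20, adjusted p = 0.0063). So did Slc18a3 (-1.26 ± 0.23, adjusted p = 0.0369) and Slc5a7 (-1.07 ± 0.16, adjusted p = 0.0162), which load and recover the motoneuron transmitter acetylcholine.

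The other large increases at day 14 were those of Ccl2 (3.47), Hamp (3.45) and Mmp3, a matrix metalloproteinase (3.22), with adjusted p between 0.00852 and 0.0254. Csrp3 and Pde6b, a phosphodiesterase subunit of photoreceptors, were not well above background in the contralateral samples and rose at least 47.0-fold and 14.6-fold (adjusted p = 0.0273 and 0.000533). The largest fall was that of Crygn, a crystallin (-3.32 ± 0.40, adjusted p = 0.00537). Aldoart2, an aldolase, was not well above background in the ipsilateral samples and fell at least 2.15-fold (adjusted p = 0.0239). Falls between -1.78 and -1.64 were those of Syndig1l, Plxdc1, Kcng1, a subunit of potassium channels, Rem2, Rprm, Slc35d3 and Scx, the transcription factor scleraxis, with adjusted p between 0.000323 and 0.0279. The meningeal and fibroblast list and the Schwann cell list, described with the other cell types, moved up at this time, but not with an estimated correlation (adjusted p = 0.281 and 0.262), and no member passed.

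Of the 21 axotomy response genes 11 rose at day 14 and 17 did over the list alone (median 1.20, adjusted p = 4.37e-24, adjusted p = 0.0302 with an estimated correlation). Ecel1 was at 3.01 ± 0.22, the neuropeptide galanin, Gal, at 2.16 ± 0.21 and Gadd45a at 1.20 ± 0.13. Gal was at 0.28 at day 3 (adjusted p = 0.816). Motoneuron markers fell in 3 of 10 members, 4 over the list alone (median -0.87, adjusted p = 0.000403, adjusted p = 0.0525 with an estimated correlation and 0.189 with the rat as a block as well). These were Slc5a7, Slc18a3 and Nefh, the neurofilament heavy chain (-1.36 ± 0.25, adjusted p = 0.0367). Pan-neuronal markers fell in 2 of 13 members, Nefl and Nefm, the neurofilament medium chain (-1.35 ± 0.19, adjusted p = 0.0115), 2 over the list alone (median -0.35, adjusted p = 0.000662, adjusted p = 0.171 with an estimated correlation). At day 3 Nefl and Nefm were at -0.11 each (adjusted p = 0.99 and 0.987). The 20 synapse genes moved down (median -0.23, adjusted p = 0.00289, adjusted p = 0.252 with an estimated correlation) with none past the threshold and 5 over the list alone. Gria3 was at -0.58 ± 0.13 (adjusted p = 0.0711). None of the 13 interneuron markers passed, and the list did not move (adjusted p = 0.531).

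All immune lists moved up at day 14. MHC class II genes rose in 6 of 10 members, 8 over the list alone (median 1.73, adjusted p = 5.69e-13, adjusted p = 0.0302 with an estimated correlation). RT1-Bb (2.54 ± 0.37), RT1-Db1 (2.46 ± 0.38), RT1-Da (2.31 ± 0.34) and RT1-Ba (2.09 ± 0.24) were among them. Complement genes rose in 4 of 18 members, 13 over the list alone (median 1.19, adjusted p = 2.4e-16, adjusted p = 0.0302 with an estimated correlation). Among them were the C1q chains C1qc (2.14), C1qa (1.80) and C1qb (1.64). Microglia markers rose in 8 of 20 members, 15 over the list alone (median 0.93, adjusted p = 9.89e-18, adjusted p = 0.0349 with an estimated correlation and 0.181 with the rat as a block as well). They include the C1q chains, Cd53 (1.42 ± 0.22) and Tyrobp, a signalling adaptor of microglia (1.26 ± 0.23). Of 15 phagocyte activation genes Lgals3, or galectin 3, rose (2.38 ± 0.46), 5 over the list alone (median 0.79, adjusted p = 6.05e-08, adjusted p = 0.0349 with an estimated correlation). Of 15 blood leukocyte markers Lyz2, a lysozyme, rose (1.62 ± 0.30), 4 over the list alone (median 0.98, adjusted p = 2.23e-06, adjusted p = 0.0302 with an estimated correlation and 0.0755 with the rat as a block as well). Of 25 cytokines and chemokines Cxcl13 and Ccl2 rose, 8 over the list alone (median 0.85, adjusted p = 4.76e-10, adjusted p = 0.148 with an estimated correlation). The 24 interferon response genes moved up (median 0.92, adjusted p = 2.78e-06, adjusted p = 0.303 with an estimated correlation) with none past the threshold and 2 over the list alone. Their list mean was 0.52, 0.48 and 1.87 in rats 4, 5 and 6, and the list did not pass without the ipsilateral sample of rat 6 (adjusted p = 0.0563).

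Reactive astrocyte genes moved up at day 14 (median 1.04, adjusted p = 4.26e-12, adjusted p = 0.0357 with an estimated correlation). Of 22 members Timp1 and Vim, or vimentin (1.48 ± 0.22), rose, 12 over the list alone, and the copper protein Cp was at 2.20 ± 0.49 (adjusted p = 0.0723, and 0.0025 with the rat as a block). Cholesterol synthesis moved down (median -0.49, adjusted p = 1.41e-09, adjusted p = 0.104 with an estimated correlation), with none of 18 members past the threshold and 13 lower over the list alone. Cyp51, a sterol demethylase, was at -0.84 ± 0.18 (adjusted p = 0.0541, and 0.0388 with the rat as a block). Oligodendrocyte and myelin genes moved down too (median -0.37, adjusted p = 5.57e-05, adjusted p = 0.201 with an estimated correlation), with none of 14 past the threshold and 3 lower over the list alone. Fa2h, which makes hydroxylated myelin lipids, was at -0.74 ± 0.16 (adjusted p = 0.0715, and 0.031 with the rat as a block). The 17 cell cycle genes moved up (median 0.56, adjusted p = 2.92e-06, adjusted p = 0.153 with an estimated correlation) with none past the threshold and 4 over the list alone. Ccnb1 was at 1.40 ± 0.31 (adjusted p = 0.0745, and 0.0291 with the rat as a block). Of 13 genes of p53 and apoptosis Casp8, an initiator caspase, rose (1.37 ± 0.24, adjusted p = 0.0279), 4 over the list alone (median 0.31, adjusted p = 6e-04, adjusted p = 0.0349 with an estimated correlation and 0.0912 with the rat as a block as well). The 9 immediate early genes moved up (median 0.27, adjusted p = 0.0226, adjusted p = 0.251 with an estimated correlation), 2 over the list alone. They did not pass with the rat as a block (adjusted p = 0.0793) or without the ipsilateral sample of rat 6 (adjusted p = 0.136). The ER stress list passed narrowly (median 0.11, adjusted p = 0.0492, adjusted p = 0.262 with an estimated correlation). It did not pass with quantile scaling (adjusted p = 0.106), without the contralateral sample of rat 5 (adjusted p = 0.133) or without the ipsilateral (adjusted p = 0.296) or contralateral (adjusted p = 0.0556) sample of rat 6. The lists of astrocyte identity (adjusted p = 0.649), oligodendrocyte progenitors (adjusted p = 0.135), scar matrix (adjusted p = 0.829) and Hox genes (adjusted p = 0.649) did not move and had no member past the threshold.

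Of the 5 lists of vessels, blood and tissue around the cord 2 moved at day 14, both up. The 10 meningeal and fibroblast markers had a median of 1.0 (adjusted p = 0.000167, adjusted p = 0.281 with an estimated correlation) with list means of 2.27, 0.64 and 0.87 in rats 4, 5 and 6. Col3a1, a fibrillar collagen, was at 2.26 ± 0.93 (adjusted p = 0.366). The 10 Schwann cell markers had a median of 0.62 and a mean of 1.01 (adjusted p = 0.00359, adjusted p = 0.262 with an estimated correlation) with list means of 2.26, 0.13 and 0.62. Egr2, a transcription factor of myelinating Schwann cells, was at 2.22 ± 0.79 (adjusted p = 0.275). The Schwann list did not pass without the contralateral sample of rat 4 (adjusted p = 0.0811). None of these markers passed singly. The lists of vascular (adjusted p = 0.715), sensory ganglion (adjusted p = 0.997) and erythrocyte markers (adjusted p = 0.601) did not move. The sensory ganglion markers had a median of -0.04 and a mean of -0.14 although the test pointed up, and 1 vascular marker was lower over the list alone.

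Long non-coding probes with MR names changed in 18 cases at day 14, 6 higher and 12 lower (72 with the rat as a block, 20 higher and 52 lower). MRAK012306 rose 6.12-fold (2.62 ± 0.16, adjusted p = 7.54e-05), MRAK004158 rose 4.17-fold (2.06 ± 0.29, adjusted p = 0.0138), and MRAK018080, not well above background in the contralateral samples, rose at least 5.72-fold (adjusted p = 0.000783). MRAK034299 (-1.84 ± 0.28, adjusted p = 0.0176), MRAK017642 (-1.32 ± 0.25, adjusted p = 0.0414) and MRuc009jdo (-1.27 ± 0.26, adjusted p = 0.0495) fell, the last not with the rat as a block (adjusted p = 0.0536). A single RefSeq non-coding probe rose, XR_006092 (0.54), and a single uc. element fell, uc.19+ (-1.06); both are named only because the counts are this small. With the rat as a block 10 RefSeq non-coding probes and 2 uc. elements passed.

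In all, 231 of 19707 probes differed between the sides at day 14, 160 higher and 71 lower, of which 188 changed at least 2-fold. With the rat as a block 677 passed, 459 higher and 218 lower, 224 of them among the 231. Leaving out any of the 6 samples lowered the count by over 1.5 times. It was 63 without the ipsilateral and 134 without the contralateral sample of rat 4, 67 and 45 for rat 5 and 53 and 44 for rat 6. It was 379 with normexp, 152 with no filter on dim probes and 398 with only the 6 samples of day 14 fitted. In settings chosen after seeing the data it was 21 without rat 6, 651 without rat 3 and 76 with the mean of the Schwann cell markers as a covariate. With the slide as a block 1006 passed, all 231 included. The 160 higher and 71 lower probes kept their direction on both slides, with medians of 1.34 and -1.07 on that of rats 4 and 5 and 1.64 and -1.26 on that of rat 6. These probes were called on the same samples, which nearly fixes their direction, so this is no separate support. Of the 28 gene lists 20 moved, 15 up and 5 down, and all 20 kept the sign of their mean on each slide and passed with the slide as a block. The lists too were called on these samples. With an estimated correlation 8 passed, and 5 with the rat as a block as well. The calls of Ucn, Ankrd1, Pde6b, Atf3, Timp1, Crygn, Syndig1l, Plxdc1, Kcng1, Nefl, Slc35d3, Scx, MRAK018080, MRAK012306, Ecel1, Gal, Gadd45a and RT1-Ba held with any 1 of the 6 samples left out. The other genes and probes given above as past the threshold at day 14 kept their sign and lost the call without at least 1 sample, at adjusted p up to 0.204. With quantile scaling the calls of Nefh (adjusted p = 0.125), C1qa (0.0765), Lgals3 (0.0701), MRuc009jdo (0.054), uc.19+ (0.0993) and Aldoart2 (0.0502) were lost, and with normexp so was that of Rem2 (0.0984), with the sign kept in all.

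**Figure D2:**
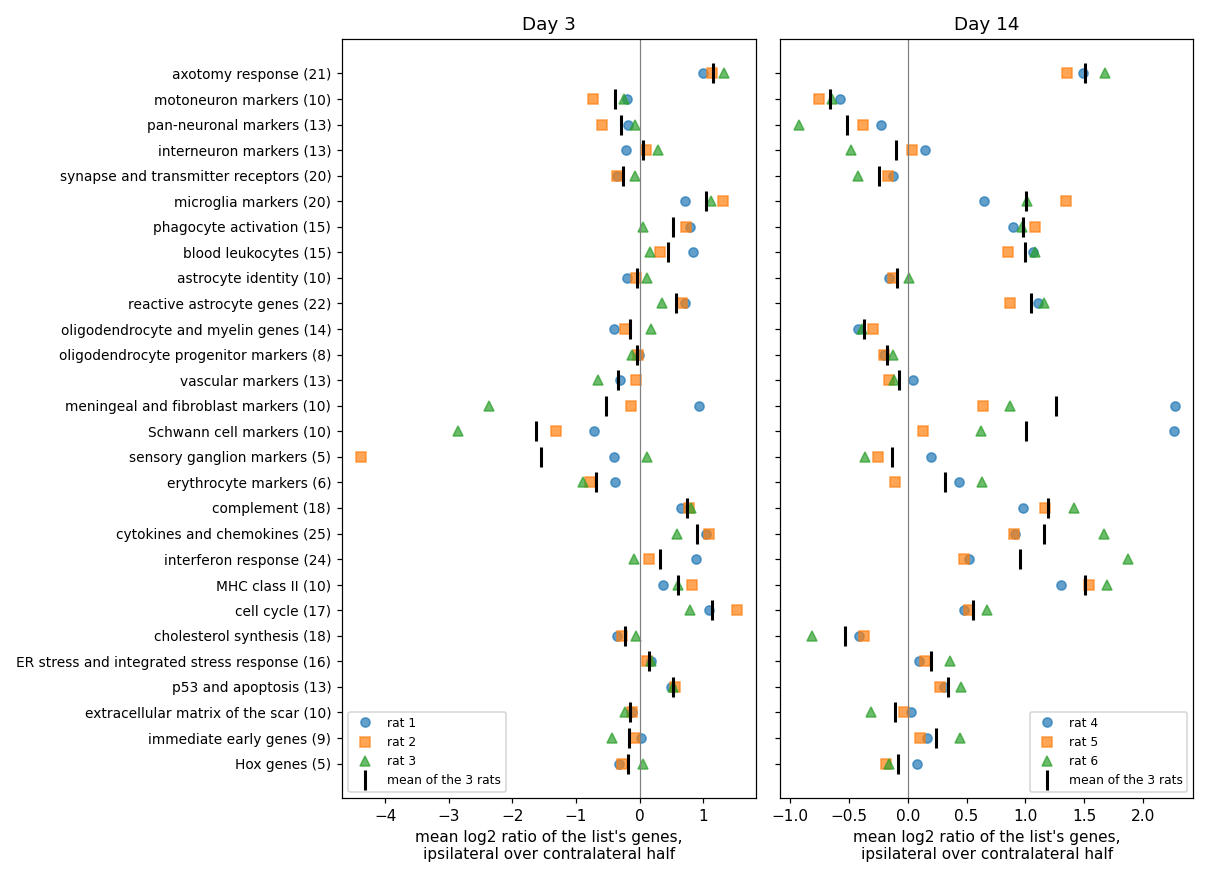
Mean log2 ratio of the ipsilateral over the contralateral hemicord over the measured genes of each of 28 lists, by rat (coloured symbols) and as the mean of 3 rats (black bars), at day 3 (left) and day 14 (right). Axotomy response genes lie above 0 in all 6 rats, from 0.99 to 1.68, and motoneuron markers lie below 0 in all 6, from -0.20 to -0.76.

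The changes on the avulsed side overlapped between the days. Of the 355 probes higher at day 3 and the 160 higher at day 14, 113 were in both sets, where 2.88 are expected of independent sets, and of the 70 and 71 lower probes 26 were in both, where 0.252 are expected. The days share no rats, but the fit uses 1 estimate of the spread per probe for both. The sets are therefore not fully independent. No probe passed in opposite directions in this fit. With the rat as a block 304 higher and 49 lower probes were in both sets, where 14.7 and 2.19 are expected. There Sostdc1 passed in opposite directions, at -3.92 at day 3 (adjusted p = 0.0274) and at 3.78 at day 14 (adjusted p = 0.0388). Across all 19707 probes, which are not independent replicates, the log2 changes of the days correlated at r = 0.499 (Spearman rho = 0.445). Of the 355 higher probes of day 3, 345 had the same sign at day 14, and of the 160 of day 14, 159 had it at day 3. For the 70 and 71 lower probes these numbers were 62 and 68.

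The difference between the days in the change from side to side was tested as an interaction. Only Lce1f passed, which rose at day 3 (4.19 ± 0.26) and was at 0.45 at day 14 (adjusted p = 0.591). The difference was -3.73 ± 0.37 (adjusted p = 0.0267, and 0.0392 with the rat as a block). In the fit without a block 560 probes had an unadjusted p under the threshold. With the rat as a block 2 probes passed, and 1506 had an unadjusted p under it. The call of Lce1f held without the contralateral samples of rat 2 (adjusted p = 0.026) and rat 3 (0.00627) and the ipsilateral sample of rat 5 (0.0271). It was lost without the ipsilateral samples of rats 1, 2, 3, 4 and 6 (adjusted p = 0.114, 0.146, 0.0564, 0.109 and 0.0816) and the contralateral samples of rats 1, 4, 5 and 6 (adjusted p = 0.0556, 0.0518, 0.145 and 0.146). Genes far apart in size between the days did not pass this test: the interaction had an adjusted p of 0.079 for Reg3g, 0.207 for Gal and Crygn, 0.439 for Nefl, 0.442 for Timp1 and 0.578 for RT1-Ba, which was at 0.48 at day 3 (adjusted p = 0.551). Of the 28 lists 15 differed between the days with the preset correlation, in a test chosen after the results of each day were seen, and none did with an estimated correlation. MHC class II genes (median difference 1.06, adjusted p = 6.28e-06, adjusted p = 0.289 with an estimated correlation) and axotomy response genes (0.31, adjusted p = 0.00118, adjusted p = 0.357 with an estimated correlation) were further up at day 14. Cell cycle genes were further up at day 3 (-0.53, adjusted p = 2.79e-07, adjusted p = 0.289 with an estimated correlation), and motoneuron markers were further down at day 14 (-0.31, adjusted p = 0.02, adjusted p = 0.303 with an estimated correlation). The motoneuron call held in only 10 of 24 alternative settings. It was lost with quantile scaling (adjusted p = 0.0567), normexp (0.117), the authors' values (0.0586), the slide as a block (0.0507) and without rat 3 (0.202), among others. The axotomy call held in 16 of the 24, and those of MHC class II and the cell cycle in 21 each. Schwann cell markers (1.84, adjusted p = 1.46e-11, adjusted p = 0.204 with an estimated correlation) and meningeal and fibroblast markers (1.78, adjusted p = 1.06e-07, adjusted p = 0.303 with an estimated correlation) had the widest differences. With the mean of the Schwann cell markers as a covariate, chosen after seeing the data, the meningeal and fibroblast list was called in the opposite direction (adjusted p = 6.43e-05) and the axotomy response did not pass (adjusted p = 0.821).

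Day 14 was also compared with day 3 on each side apart. In the ipsilateral hemicord the largest increases were those of Gdf6, a growth factor of the BMP family not well above background at day 3, which was at least 29.2-fold higher (adjusted p = 0.000914), and Tcl1a (6.43 ± 0.94). Next came the potassium channel Kcnh7 (5.99 ± 0.64), the olfactory receptor Or52z12 (5.87 ± 1.13) and the trace amine receptor Taar5 (5.76 ± 1.01). The largest decreases were those of Reg3b (-4.75 ± 0.75, adjusted p = 0.0015), the mitotic gene Pimreg (-3.56 ± 0.57), Serpinb2 (-3.39 ± 0.60) and Crygn (-3.36 ± 0.40), and Kiss1, the kisspeptin precursor, was not well above background at day 14 and at least 4.86-fold lower (adjusted p = 0.00943). In the contralateral hemicord Gdf6 was at least 36.9-fold higher. There Or52z12 (5.78 ± 1.13), Taar5 (5.65 ± 1.01), the olfactory receptor Olr1564 (5.64 ± 1.14) and Tcl1a (5.53 ± 0.94) were also higher. Sostdc1, a BMP antagonist (-4.49 ± 0.93), Slc36a2 (-3.89 ± 1.16), the tight junction gene Cldn19 (-3.51 ± 0.93), Sfrp5 (-3.47 ± 0.92) and Prx (-3.30) were lower. Of these 10 contralateral calls Slc36a2, Cldn19, Sfrp5 and Prx were lost without at least 1 sample, at adjusted p up to 0.0929.

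Nearly the same number of probes differed between the days on the uninjured side as on the avulsed side, 9571 (7106 higher and 2465 lower at day 14) and 9608 (6831 higher and 2777 lower). Of the 9608, 9491 had the same direction in the contralateral hemicord and 7959 passed there too. The fit takes the hemicords of a rat as independent. Between the 2 slides of day 3 alone 8064 probes passed, 6134 higher and 1930 lower on that of rat 3. This limma fit, chosen after seeing the data, used the day 3 samples and fitted the side as well. Slide 2 holds rat 3 alone, so it mixes slide and rat. The counts between days are therefore not a measure of time alone. In the simulated data 13% of the ipsilateral and 8.26% of the contralateral calls between days were unchanged probes. There 200 probes were changed and no slide effect was drawn. Such a share depends on how many probes change, so it is not an error rate for the counts given here. Each slide holds 1 day, so day and slide are told apart only by the spread between slides of 1 day. With the slide as a random block 5923 probes passed ipsilaterally and 5696 contralaterally. That fit uses 1 correlation (0.617) for all probes, and 2 slides a day leave the spread between slides poorly known. These counts can therefore be too high. The excess of higher calls came with the scaling. With quantile scaling 3499 were higher and 5048 lower ipsilaterally (40.9% higher, against 71.1%) and 3991 and 4876 contralaterally (45.0%, against 74.2%). The median of all probes moved from 0.30 to -0.10 and from 0.30 to -0.08, a shift of -0.40 and -0.38. Without the ipsilateral samples of rats 1 and 2 in turn the ipsilateral count was 5882 and 5619, and without the contralateral samples of rats 1 and 2 the contralateral count was 6037 and 5733. Long non-coding classes were higher at day 14 relative to mRNAs: the median ipsilateral change was 1.20 for RefSeq non-coding probes, 1.79 for uc. elements, 0.69 for MR names and 0.14 for mRNAs, and with quantile scaling 0.59, 0.74, -0.09 and -0.16, so that MR names and mRNAs turned sign. On the contralateral side the medians were 1.23, 1.80, 0.73 and 0.13, and 0.64, 0.77, 0.00 and -0.16 with quantile scaling. With normexp they were 0.26, 0.18, -0.04 and -0.13 ipsilaterally and 0.31, 0.20, 0.00 and -0.13 contralaterally. The change between days also varied with the filter on dim probes. The ipsilateral median of all probes was 0.446 with no filter and 0.142 with only probes above background on all arrays. Of 962 uc. elements 424 passed the main filter, against 13088 of 15323 mRNA probes. A difference by class was therefore not separated from one by brightness or slide.

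**Figure D3:**
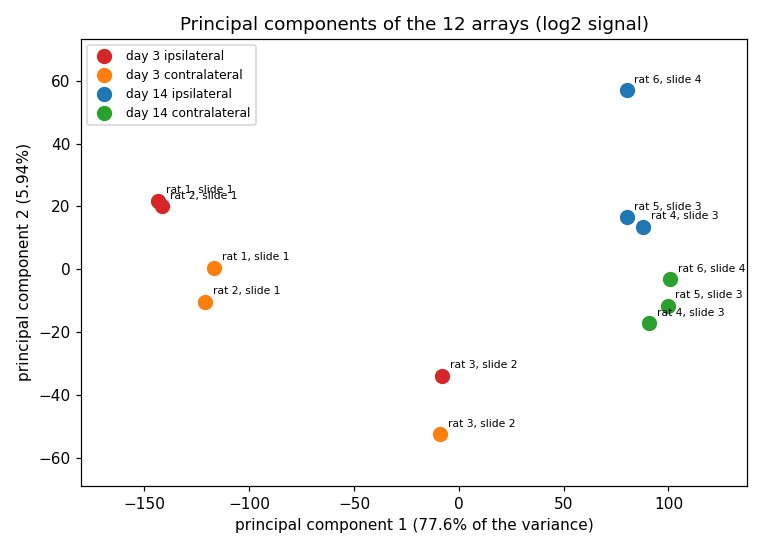
First and second principal components of the log2 signals of the 12 samples, with the share of the variance on each axis, coloured by group and marked with rat and slide. The first component (77.6% of the variance) runs from -143.6 to -116.7 for rats 1 and 2, lies at -8.8 and -7.9 for rat 3 and from 80.0 to 100.9 for the day 14 rats.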

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

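The list tests on the difference between days, the comparison of slides, the Schwann cell marker covariate with its effect on other calls, the marker change at day 14 and both tests on motoneuron markers were chosen only after the results were seen. Quantile scaling was chosen before, and its use as a test of the first pattern after. The single gene whose change from side to side differed between the days was Lce1f (-3.73 on the log2 scale, day 14 minus day 3). Of the 28 lists 15 differed between the days with camera's preset correlation, all given here as the median log2 difference. Those further up at day 14 were Schwann cell markers (1.84), meningeal and fibroblast markers (1.78), sensory ganglion markers (1.42, adjusted p = 0.00853, adjusted p = 0.397 with an estimated correlation), MHC class II (1.06), interferon response (0.58, adjusted p = 0.00533), complement (0.56, adjusted p = 0.00807), immediate early genes (0.52, adjusted p = 4.71e-05), phagocyte activation (0.42, adjusted p = 0.00853), reactive astrocyte genes (0.40, adjusted p = 0.00244), vascular markers (0.33, adjusted p = 0.0288) and axotomy response (0.31). Those further down were cell cycle (-0.53), motoneuron markers (-0.31), cholesterol synthesis (-0.29, adjusted p = 3.15e-05) and oligodendrocyte and myelin genes (-0.19, adjusted p = 0.00895). With an estimated correlation none of the 15 passed, the lowest adjusted p being 0.204 and the highest 0.629, and fry called 0 lists by its p for 1 direction. By its mixed p it called MHC class II (adjusted p = 0.0423). Of 24 alternative settings the call held in the same direction in 21 for MHC class II, cell cycle and immediate early genes, in 20 for Schwann cell, meningeal and fibroblast and cholesterol synthesis, in 18 for sensory ganglion and reactive astrocyte, in 16 for axotomy response, in 14 for interferon response, in 13 for phagocyte activation, in 12 for complement and for oligodendrocyte and myelin, in 11 for vascular and in 10 for motoneuron genes. The interferon response was lost without the ipsilateral sample of rat 6, where the test pointed down (adjusted p = 0.354), without rat 3 (0.256) and without rat 6 (0.493), and complement with quantile scaling (0.087), normexp (0.117) and the authors' values (0.0878). The other 13 lists did not pass, at adjusted p from 0.0553 (pan-neuronal markers) to 0.92 (synapse, microglia and scar matrix), although erythrocyte markers (median 1.18, adjusted p = 0.16) did with the rat as a block (adjusted p = 0.000608, and 0.341 with an estimated correlation as well). In 3 of these the signs part: synapse genes have a median and mean of 0.02 with a test pointing down, microglia markers a median of -0.11 with a test pointing up, and scar matrix genes a median of -0.07 and a mean of 0.04.

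The first pattern is the number of probes that differ between day 14 and day 3. An injury response of the ipsilateral side alone needs the contralateral side to move far less, but over the probes called ipsilaterally the slope of the contralateral on the ipsilateral change was 0.903. With quantile scaling 8547 ipsilateral probes passed, so a count of this size was not particular to scaling to the 75th percentile. The excess of higher calls does rest on that scaling: 3499 were higher and 5048 lower, in place of 6831 and 2777. The calls were thus in part not the same ones. A similar total therefore does not exclude the scaling as a source of many of them. A difference between slides and scans stays open. The contralateral difference between the slides of day 3, rat 3 minus rats 1 and 2, was set against an ipsilateral difference between days. The latter was day 14 minus rats 1 and 2 only, without rat 3. The 2 correlated at r = 0.736 across probes. Both subtract rats 1 and 2, whose hemicords deviated together, so part of this correlation is built in. Slide 2 holds rat 3 alone, so slide and rat cannot be told apart. A change with time common to both sides stays open too, as each slide holds 1 day and no uninjured rats were analysed here.

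The second pattern is the fall of Slc36a2, Sfrp5, Abca15 and Mrap on the ipsilateral side at day 3. With the mean of the Schwann cell markers as a covariate the changes of Slc36a2, Sfrp5 and Mrap went from -5.49, -5.33 and -3.32 to -2.18, -3.08 and -1.41, least for Sfrp5 (median -5.33 to -2.18), as peripheral nerve tissue in unequal amounts in the hemicords would give (Abca15 has only a bound and was left out), while the other 66 lower probes outside the Schwann list kept a median share of 0.926 of their change. The SEs of the 3 genes went from 0.70 to 1.16 without the covariate to 0.48 to 0.83 with it, but the loss of their calls (adjusted p = 0.279 to 0.435) is not specific, since the adjusted p depends on all probes and only 16 in place of 425 passed. Removal of the avulsed roots from the ipsilateral side predicts fewer Schwann cell transcripts there at day 14 too. The mean over rats of the Schwann cell marker change was 1.005 (SE 0.645, n = 3) at day 14, so this cannot be told apart from a change of the tissue itself with 3 rats a day.

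The third pattern is the fall of motoneuron markers on the ipsilateral side at day 14. Dilution of neuronal RNA by other cells would lower interneuron markers as much. The motoneuron list minus the interneuron list was -0.558 (SE 0.2, n = 3 rats). In rats 4, 5 and 6 the motoneuron list means were -0.58, -0.755 and -0.642 and the interneuron list means 0.142, 0.037 and -0.483. In rat 6 both lists were lower, and the pan-neuronal markers lay further down (-0.927). With 3 rats, and a rule set after the values were seen, this does not exclude dilution. Lower transcript levels in surviving motoneurons and loss of motoneurons stay open too. The prediction set for loss was that all 10 measured markers are lower on the ipsilateral side, and 8 were. A marker that other cells also make, or that injury raises, need not fall with loss. The markers that were not lower therefore do not speak against it. Hemicord RNA without cell counts cannot tell these apart.

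Other splits of the same 6 arrays into 3 and 3, of which there are 10, are too few for a share under 0.05, so only the real value and the highest other are given. At day 3, 2 of the 10 splits gave at least as many probes, the real one (425) and another with 1537, which sets both sides of rat 2 and the ipsilateral side of rat 1 against both sides of rat 3 and the contralateral side of rat 1. That split calls several times the real count, which points to a structure of the samples. The other 3 splits that set 3 samples of slide 1 against the rest gave 203, 3 and 2. Among the 4 splits that part all pairs of hemicords the highest other count was 0. For lists at day 3, 2 of the 10 splits gave as many, 16 for the real one and 20 for the one that swaps the sides of rat 3, which also parts all pairs. At day 14 only 1 split, the real one, gave as many probes (231, highest other 0) and lists (20, highest other 17). The other day 14 splits called 5 to 17 lists while calling 0 probes. The preset correlation thus calls many lists in groupings other than the real one. These splits keep part of the differences between sides and rats, so they do not give a rate of false calls. For the interaction only 1 split gave as many probes (1, highest other 0) and lists (15, highest other 14). For the days only 1 split gave as many ipsilaterally (9608, highest other 0) and contralaterally (9571, highest other 0).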

How the results depend on the processing

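The slide as a random block, left-out rats, the slide with 2 rats, the Schwann marker covariate and the interaction list tests were chosen only after the data were seen. The cause of a change was not tested unless given. Probe counts for day 3 (main value 425) were 261 with quantile scaling, 277 with the authors' values, 641 with an unadjusted p and at least 2-fold, 1093 with the slide as a block, 829 with the rat as a block, 1484 with the rat as a random block, 1188 with the slide as a random block, 16 with only the 2 groups' arrays, 272 without rat 6, 16 with the Schwann covariate and 0 in limma on only the slide with 2 rats, where 3194 had an unadjusted p under 0.05 and fewer arrays were fitted. For day 14 (231) they were 379 with normexp, 152 with no filter, 530 with an unadjusted p and at least 2-fold, 1006 with the slide as a block, 677 with the rat as a block, 1666 with the rat as a random block, 1214 with the slide as a random block, 398 with only the 2 groups' arrays, 651 without rat 3, 21 without rat 6, 60 on the slide with 2 rats and 76 with the Schwann covariate. For the interaction (1, Lce1f) they were 5 with quantile scaling and 5 with the authors' values (Lce1f, MRuc008qeu, Cgm4, NM_001105894 and NM_001107939 in both), 6 with normexp, 5 with probes above background on all arrays (Lce1f, Mme, Cyp4b1, NM_001105894 and NM_001107939), 12 with the slide as a block, 2 with a variance trend and 2 with the rat as a block (Lce1f and NM_001105894 in both), 248 with an unadjusted p and at least 2-fold, 45 with the rat as a random block, 14 with the slide as a random block, 4 without rat 3 (Lce1f, MRuc008qeu, Reg3a and AB455106), 0 without rat 6 and 0 with the Schwann covariate (469 and 394 with an unadjusted p under 0.05 in limma). These names were taken after the values were seen. For the days they were 5772 ipsilaterally and 5830 contralaterally (9608 and 9571) with an adjusted p and at least 2-fold, 6184 and 6208 with an unadjusted p and at least 2-fold, and 5923 and 5696 with the slide as a random block. The slide as a fixed block was not run for the days because each slide holds 1 day. Leaving out 1 array gave 120 to 554 at day 3, 44 to 134 at day 14, 0 to 3 for the interaction, 5619 to 11304 for the days ipsilaterally and 5733 to 11706 contralaterally. In such a fit a group is left with 2 arrays.

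Of the lists, 16 moved at day 3, but 0 with an estimated correlation, 0 with the rat as a block and an estimated correlation and 8 with fry (its p for 1 direction, here and below). At day 14 20 moved, 8 with an estimated correlation and 5 with the rat as a block and an estimated correlation, where microglia (adjusted p = 0.181), blood leukocytes (0.0755) and p53 and apoptosis (0.0912) were lost. In the interaction 15 did, 0 with an estimated correlation, 0 with fry, 0 with the rat as a block and an estimated correlation, 9 without rat 3 and 9 with the Schwann covariate. Leaving out 1 array gave 13 to 16, 17 to 20 and 7 to 17. Interaction calls were lost with quantile scaling for phagocyte activation (adjusted p = 0.0785), oligodendrocyte and myelin (0.193), complement (0.087) and motoneuron genes (0.0567), with normexp for these (0.136, 0.17, 0.117 and 0.117) and vascular markers (0.0598), and with the slide as a block for motoneuron (0.0507) and sensory ganglion markers (0.0622). Among the calls lost on only the slide with 2 rats were those of sensory ganglion markers at day 3 (0.115). At day 14 those of pan-neuronal (0.073), synapse (0.115) and immediate early genes (0.188) were among them. With the Schwann covariate 4 of the 15 interaction calls were kept. Called in the opposite direction, down, were meningeal and fibroblast markers (adjusted p = 6.43e-05) and the interferon response (0.004). Lost were axotomy response (0.821), phagocyte activation (0.472), reactive astrocyte (0.508), oligodendrocyte and myelin (0.893), vascular (0.893), Schwann cell (0.893), sensory ganglion (0.609), complement (0.0689) and cholesterol synthesis (0.377). New were microglia (up, 2.73e-05), erythrocyte (down, 0.0109) and cytokines and chemokines (down, 0.0107). With the Schwann covariate the day 3 calls of Schwann cell (adjusted p = 0.987), vascular (0.364) and sensory ganglion markers (0.307) and the day 14 calls of Schwann cell (0.878) and meningeal and fibroblast markers (0.64), ER stress (0.151) and immediate early genes (0.057) were lost, and meningeal and fibroblast markers were called up at day 3 (8.56e-06, main value 0.187 down) and oligodendrocyte and myelin genes down (0.00596). The covariate is made from a list tested here.

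Of the genes given singly, 135 results that passed and 23 that did not were refitted under the same alternatives. The former gave 2665 values, of which 1947 kept direction and call, 718 kept direction only and 0 reversed. The latter gave 478 values, 395 of them with the same direction and no call, 78 with the same direction and a call, and 5 reversed. The reversed ones were all uncalled and near 0 at day 3: Nefl, main value -0.11, was at 0.066 without the contralateral array of rat 2 (range -0.28 to 0.066 over single arrays left out) and at 0.006 with the Schwann covariate; Nefm, main value -0.11, was at 0.011 without the contralateral array of rat 2 (range -0.28 to 0.011); and Gfap, main value 0.18, was at -0.009 without rat 3 and at -0.009 on only the slide with 2 rats. Apart from the counts and calls given beside their results, the rat as a block changed no other call. The median signal was 4.66 to 7.32 times the local background at day 14 and 8.2 to 13.2 times at day 3, while 74.7% to 82.4% and 71.8% to 75.1% of probes were well above background. Changes of probes not above background are known only as bounds.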

Other observations

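Genes given here were picked after their values were seen, except that Adcyap1, Vip, Gap43 and Crh belong to the axotomy response list. Adcyap1, which encodes the neuropeptide PACAP, rose on the ipsilateral side at both days (1.84 ± 0.35, adjusted p = 0.027 at day 3, and 2.88 ± 0.35, adjusted p = 0.00573 at day 14, higher in 3 of 3 rats each). Its relative Vip rose as well (1.75 ± 0.23, adjusted p = 0.00488, and 1.42 ± 0.23, adjusted p = 0.0218). At day 14 Gap43, a protein of growing axons (1.20 ± 0.23, adjusted p = 0.0407), and Crh, the peptide of the same family as urocortin (1.11 ± 0.20, adjusted p = 0.0305), rose, and so did Cd74, the invariant chain of MHC class II (2.10 ± 0.35, adjusted p = 0.0254). With any 1 of the 6 samples left out the calls of Vip at day 3 and Adcyap1 at day 14 held. At day 3 that of Adcyap1 was lost in 5 of 6 such fits (adjusted p up to 0.125) and with quantile scaling (1.66, adjusted p = 0.0865). At day 14 those of Gap43 (6 of 6, up to 0.173), Crh (6 of 6, up to 0.159, and 0.0598 with quantile scaling), Cd74 (5 of 6, up to 0.122) and Vip (4 of 6, up to 0.114) were lost. Gfap, the astrocyte filament gene, was at 0.18 ± 0.16 at day 3 (adjusted p = 0.875) and 0.15 ± 0.16 at day 14 (adjusted p = 0.89).

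Sostdc1, a secreted antagonist of BMP signals, was at -3.92 ± 0.93 at day 3 (adjusted p = 0.0678, and 0.0274 with the rat as a block) and at 3.78 ± 0.93 at day 14 (adjusted p = 0.0982, and 0.0388 with the rat as a block). The ratio was -2.30, -3.94 and -5.53 in rats 1, 2 and 3 and 5.24, 2.57 and 3.52 in rats 4, 5 and 6, but the interaction did not pass (adjusted p = 0.261). The sensory ganglion markers lay far lower on the ipsilateral side in rat 2 (mean -4.38) than in rat 1 (-0.40) or rat 3 (0.11).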
